A study of Mus musculus with 8 samples.

How the data were processed

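Chromatin accessibility was measured by ATAC-seq in long-term haematopoietic stem cells (HSC) sorted from mouse bone marrow. In this assay a transposase cuts open chromatin and inserts sequencing adapters, so that fragments pile up where DNA is accessible. Per the labels' protocols, 5000 nuclei per library were incubated with Nextera transposase for 30 min at 37 °C, and the tagged fragments were amplified by PCR. The labels describe 8 libraries in 4 groups of 2, named by a Vav1-cre iMOS Bcl11a genotype (MUT or WT) and a sorted population (T1 or T2). The age is given as 2 to 3 months in a characteristic and as 3 months in the description of the design. What separates T1 from T2, and which of them carries a Bcl11a transgene, is not given in the sources used here, so the populations keep their labelled names. The libraries within a group are numbered 1 and 2, and nothing in the labels says that they came from separate animals. Whether T1 and T2 libraries of a genotype came from the same animals is not given either. Tests over all libraries of a genotype or population may thus count an animal more than once. P-values of permutation tests over libraries therefore measure only the spread between these libraries. Those of Fisher's exact tests and of random draws take regions or genes as units and do not measure that spread.

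The authors deposited 1 peak list per library, so peaks were called per sample and not on pooled samples. Bowtie2, SAMtools, MACS2 and the mm10 build are named in the submitters' processing notes, with no versions, and whether cut sites were shifted for the transposase is not given in the sources used here. Each peak in the deposited lists has a position, a score, a fold enrichment (a ratio of the summit to its local background), a −log10 p-value, a −log10 q-value and a summit offset, all as the authors' peak caller wrote them. The lowest deposited −log10 q-value was 3.00, so the lists hold peaks at a q of 0.001 or below. Fold enrichment is the authors' own value per peak and is used only to describe, rank or filter peaks within a list. A peak list records presence above a threshold: a region that is missing from a list may be accessible there below that threshold.

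Read totals are not part of the lists, so depth was recovered from the deposited ratio and −log10 p-value of each peak. MACS2 computes the ratio as the summit pileup plus 1 over the local background plus 1, and the p-value as a Poisson tail, so both quantities can be solved for. The pileup came out as a whole number that returned the deposited −log10 p-value within 0.001 for at least 99.9986% of the peaks in every library (5 to 7 peaks per library with a −log10 p-value above 300 were left out). The lowest local background in a library is the genome-wide background of the peak caller and was taken as its relative depth. It ranged from 1.89 to 3.38 fragments per position, a ratio of 1.79. In simulated lists, 100% of 14899 pileups were recovered exactly.

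Peaks on chromosomes 1 to 19 and X were merged into regions when they overlapped by at least 1 bp, over all 8 lists. A region was called in a library when a peak of that library overlapped it by at least 1 bp. A region was gained in a first group against a second when it was called in both libraries of the first and in neither of the second, and lost in the reverse case. With 2 libraries against 2 there is no test per region, so the number gained and lost was set beside the same number for the other 2 splits of the same libraries. For all MUT against all WT libraries the count was set beside the other splits of the 8 libraries into 4 and 4, of which there are 35 with the real split. The mean number of peaks was compared with an exact two-sided permutation test over 70 arrangements (smallest p 0.0286). The similarity of 2 lists was the Jaccard index, shared base pairs over the union, and same-group pairs were compared with other pairs by an exact one-sided permutation test over all divisions of the libraries into pairs (smallest p 0.00952). Fisher's exact test, two-sided, was used for counts of regions, with Benjamini-Hochberg adjustment, and regions are not independent replicates.

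Gene names and coordinates came from a RefSeq gene table of assembly GRCm38.p6, the same build as mm10, with 21627 protein-coding genes on the chromosomes used. The table gives gene spans without strand, exons or transcript starts. Regions were therefore assigned to the gene whose span holds their midpoint, or otherwise to the gene with the nearest span end within 50 kb, in place of the transcript start that had been planned, and promoter shares became shares within 1 kb of either end of a gene span. Whether a region inside a gene is exonic or intronic was not analysed here. A planned count of transcription factor motifs was not run, because it needs a genome sequence. Of 335 entries in 13 gene lists fixed before the data were examined, 334 matched the table (all but Mx1). The lists cover HSC identity, HSC aging, B lymphoid, T and NK lymphoid, granulocyte and monocyte, erythroid, megakaryocyte and platelet, cell cycle and survival, inflammation and NF-kB, interferon response, AP-1 and immediate early, TGF-beta and niche signalling, and stromal and endothelial genes. For each list, gained against lost regions assigned to its genes were compared with those of all other genes, over 52 tests (13 lists in 4 comparisons).

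The genes named in the text follow a rule that was fixed before the data were examined. Bcl11a comes first, with all peaks within 5 kb of its span. In each comparison of 2 groups and each direction come the 8 regions with the highest smaller fold enrichment of the 2 calling libraries, at most 1 per gene, and then up to 8 further genes of the fixed lists in the same order; for all MUT against all WT the number is 10 in each part. List members given as examples without a fold enrichment of their own were chosen outside this rule, after their values were seen, as were genes of the sex chromosomes and of regions with opposite directions in T1 and T2. A few genes that the rule selects are not reported here, while the counts of their lists include them.

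Alternatives chosen along with the design were a stricter q of 1e-05, the same number of peaks from each list (the 62232 with the highest −log10 p), a region covered over at least 50% of its length, windows of 125 bp on each side of the summit, autosomes only, each library left out in turn, a block by replicate number, assignment within 10 kb, 10000 random gene lists matched on the number of assigned regions, and gene ends within 2 kb. Thinning to equal depth and leaving out chromosome 14 were added after the data had been seen. In the thinning, each summit pileup was drawn down at random to the lowest background of the 8 libraries, and peaks were kept that still reached a −log10 p of 4.90, the highest of the lists' own minima. Peaks were not called anew, so this matches the background only, and the thinned lists still held 62231 to 70609 peaks. The counting was tested on simulated lists: all of 200 regions planted per direction were recovered in each of the 4 comparisons of 2 groups (over 86341 to 86451 regions), and 2 to 2.5% of random sets of regions fell under 0.05. The planted calls were set to meet the definition of gained or lost, so their recovery checks the code alone. The random sets were drawn region by region and not by gene. They therefore do not give the error rate of the gene lists. The software was Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.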

Results

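Chromatin accessibility was profiled in HSC of Vav1-cre iMOS Bcl11a mice, in which Vav1-cre acts in blood cells, to ask what Bcl11a does within HSC and what its overexpression does to the wild-type HSC beside them. Bcl11a encodes a zinc-finger transcription factor that represses fetal globin genes and is needed for lymphoid development. A T1 and a T2 population were sorted from MUT and from WT mice, with 2 libraries in each of the 4 groups. MUT T1 libraries held 74192 and 63976 peaks (mean 69084 ± 7224, SD, n = 2) and MUT T2 libraries 74785 and 71239 (73012 ± 2507). WT T1 libraries held 71683 and 72719 (72201 ± 733) and WT T2 libraries 67271 and 62232 (64752 ± 3563). The genome background, a measure of depth, was 3.38 and 2.03 fragments per position in MUT T1, 3.21 and 3.10 in MUT T2, 3.24 and 3.29 in WT T1, and 2.45 and 1.89 in WT T2. MUT T1 replicate 2 and both WT T2 libraries were therefore the shallowest, and they stood apart from the other 5. The median width of peaks was 516 to 626 bp per library, and peaks covered 38.6 to 52.9 Mb.

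**Figure D1:**
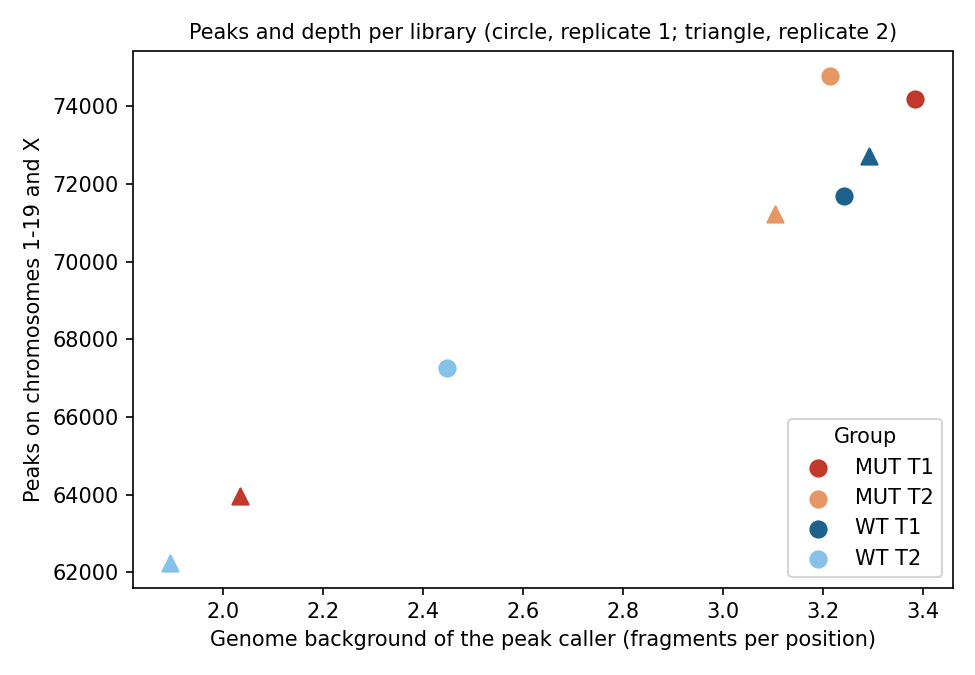
Number of peaks on chromosomes 1 to 19 and X (vertical axis) against the genome background of the peak caller in fragments per position (horizontal axis) for each of the 8 libraries, coloured by group, with circles for replicate 1 and triangles for replicate 2. The 3 libraries with a background of 1.89 to 2.45 have 62232 to 67271 peaks, and the other 5 have 71239 to 74785.

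The 8 lists merged into 90736 regions, of which 49577 (54.6%) were called in all 8 libraries and 10513 (11.6%) in only 1. The midpoint lay within 1 kb of the end of a protein-coding gene for 25.4% of the regions called in all 8 libraries and for 5.07% of those called in 1. The HSC transcription factor genes Mecom, Prdm16, Meis1 and Runx1 had 25, 17, 13 and 12 regions called in every library. The mean number of peaks was 71048 ± 4963 in MUT and 68476 ± 4786 in WT libraries (SD, n = 4 each), a difference of 2572 that was within the spread between libraries (exact two-sided permutation p = 0.486, Benjamini-Hochberg adjusted p = 0.657). T1 libraries had 70643 ± 4562 and T2 libraries 68882 ± 5392 peaks (n = 4 each, exact permutation p = 0.657, Benjamini-Hochberg adjusted p = 0.657). Libraries of the same group had a mean Jaccard index of 0.706 and other pairs 0.695, a difference of 0.0103 (exact one-sided permutation p = 0.219). The MUT T1 pair had the lowest index of all (0.644) and the WT T1 pair the highest (0.745). Without MUT T1 replicate 1 the difference was 0.0367 (exact permutation p = 0.00952), and without MUT T1 replicate 2 it was 0.0225 (exact permutation p = 0.0286). Either omission takes the MUT T1 pair, the lowest of all, out of the same-group mean, so a rise follows from it. With any other library left out the difference was −0.00244 to 0.0129 (exact permutation p = 0.295 to 0.629). The difference between like and unlike pairs was 5.54e-05 for genotype (exact permutation p = 0.314), −0.00213 for population (exact permutation p = 0.429) and 0.00584 for replicate number (exact permutation p = 0.2), none of which passed.

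Among the fixed lists, a region that reached within 1 kb of a gene end was called in all 8 libraries for 27 of 30 HSC identity genes (90%) and 27 of 30 HSC aging genes (90%). The share was 88% for megakaryocyte and platelet genes, 84% for inflammation and NF-kB genes, 95.8% for interferon response genes, 96% for AP-1 and immediate early genes, 96% for TGF-beta and niche signalling genes, 84% for cell cycle and survival genes and 72% for stromal and endothelial genes. It was lower for B lymphoid genes (52%), T and NK lymphoid genes (56%), granulocyte and monocyte genes (56%) and erythroid genes (60%), against 64.8% of all 21627 protein-coding genes. Each of these lists holds 25 genes, and the differences in share were not tested. Genes of committed cells with no region at either end in any library included the recombinase genes Rag1 and Rag2, Cd3e of T cells, Elane and S100a8 of neutrophils, the erythroid factor gene Gata1, the globin gene Hba-a1 and Cdh5 of endothelium. These 8 examples were chosen after their values were seen. Genes of other lists had no region at either end as well, such as Mcl1 and Bcl2l1 (cell cycle and survival), Nfkb2 (inflammation and NF-kB) and Egr2 (AP-1 and immediate early). Lack of such a region is thus not particular to genes of committed cells. A count by the midpoint of a region gave lower shares (83.3% for HSC identity, 44% for B lymphoid and 60.8% for all genes), because the midpoint of a wide region can lie beyond 1 kb. The reach of a region was adopted after these values had been seen.

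Bcl11a itself was accessible in all 8 libraries. Its span on chromosome 11 (24076564 to 24173558, mm10) with 5 kb on each side held 16 regions, and 6 of them were called in every library. One of these, from 24076085 to 24077768, lies over an end of the gene, and the others start at 24080689, 24111630, 24139163, 24144270 and 24161897. The last had the highest fold enrichment at the locus in each library (6.49 to 8.37). Libraries had 10 and 8 peaks there in MUT T1, 10 and 9 in MUT T2, 12 and 10 in WT T1, and 9 and 8 in WT T2. No region at Bcl11a was called in all MUT and no WT libraries or the reverse, and none was called in both libraries of 1 group and in no other library. The region starting at 24131709 was called in both MUT T1 libraries (2.53 and 3.33), WT T1 replicate 1 and no other, so it was gained in MUT T1 against MUT T2. The region starting at 24074175 was called in both WT T1 libraries (2.04 and 2.10), MUT T1 replicate 1, MUT T2 replicate 2 and neither WT T2 library, so it was gained in WT T1 against WT T2.

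**Figure D2:**
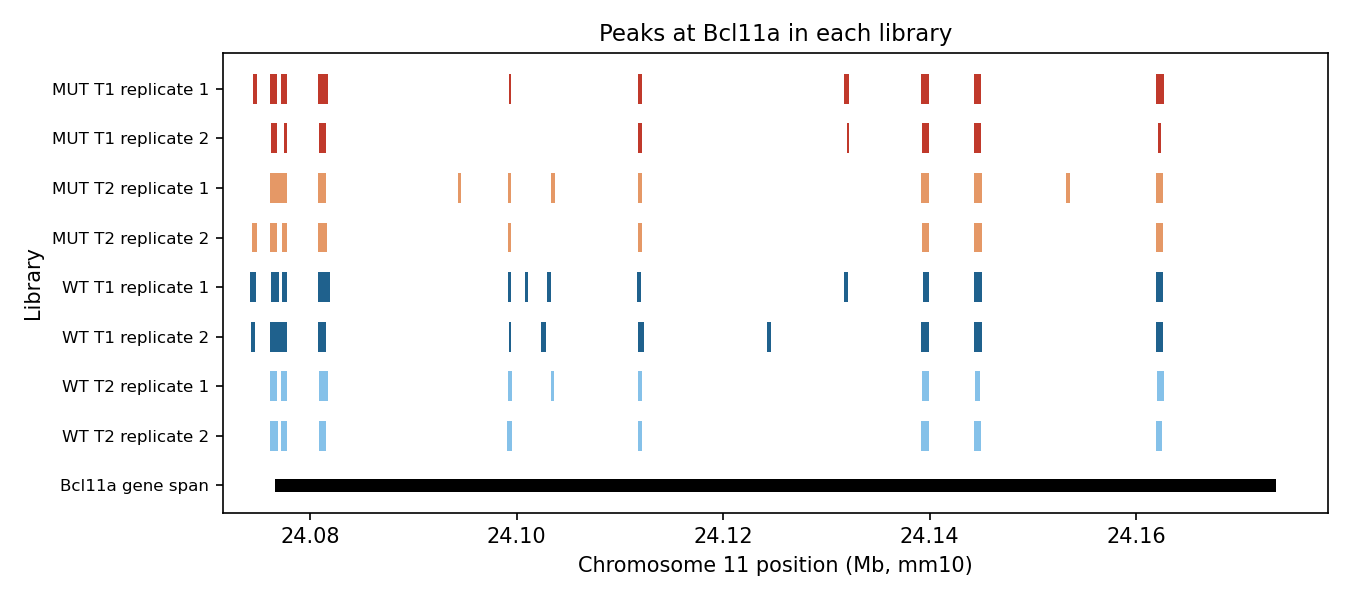
Peaks (bars) at Bcl11a in each of the 8 libraries along chromosome 11 in Mb of mm10, with the gene span drawn beneath. The 6 regions called in every library include one over a gene end that starts at 24076085, and peaks per library number 8 to 12.

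MUT T1 against WT T1 asks how the T1 population of MUT mice differs from that of WT mice. Regions called in both MUT T1 and neither WT T1 libraries lay inside Itga6, which encodes an integrin subunit that binds laminin (chromosome 2, 71852136 to 71852794, smaller fold enrichment 10.9), near Slc25a54, a mitochondrial carrier gene (12.3), near the receptor phosphatase gene Ptprt (10.5) and inside Lmo3 (9.81). Gm3739, Sh2d4a, Paqr9 and Dennd1a completed the 8 strongest, at 9.23 to 9.81. Of these, the regions at Slc25a54 (12.4 in each) and Sh2d4a (11.9 and 7.25) were also called in both WT T2 libraries. They are absent from WT T1 and do not separate the genotypes. Those at Itga6, Ptprt and Lmo3 were called in no WT library. Regions called in both WT T1 and neither MUT T1 libraries lay inside Mid1, a ubiquitin ligase gene that spans the pseudoautosomal boundary in the mouse (X, 169978759 to 169979561, 11.3), inside Galm (10.5), near Anxa1, an annexin gene (10.3), and inside Acvr1, a type I receptor gene for bone morphogenetic proteins (9.25). Cntln, Spcs3, Rims2 and Syap1 followed at 8.85 to 9.67. In total 1140 regions were gained and 1934 lost.

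Among the fixed lists in MUT T1 against WT T1, TGF-beta and niche signalling genes had 1 gained and 10 lost regions, the lost ones including Cxcr4 (4.66), the receptor that holds HSC in the marrow, Acvr1, Tgfbr3 and Angpt1. The gained share of that list was 9.09%, against 35.9% for regions at other genes (Fisher's exact test p = 0.110, Benjamini-Hochberg adjusted p = 1.00 over 52 tests). HSC identity genes had 11 gained and 13 lost regions, with gains at Runx1 (4.56) and Kit (4.51), losses at Gfi1b (5.59) and Fgd5 (5.13), and 1 gain at Gfi1b as well. Gained and lost regions numbered 2 and 7 for inflammation and NF-kB genes, with gains at Il1b (5.25) and Nfkbiz (4.86) and losses at another Il1b region (5.60) and at Il6 (5.13), and 1 and 6 for cell cycle and survival genes, with a gain at Bcl2 (4.62). They numbered 3 and 3 for T and NK lymphoid genes, where Themis had 1 gained (5.02) and 1 lost (7.46) region. They numbered 1 and 4 for B lymphoid genes (gain at Pou2af1, 4.56), and 2 and 5 for megakaryocyte and platelet genes (loss at F2rl3, 5.88). The others were 1 and 2 for HSC aging, 0 and 2 for granulocyte and monocyte, 3 and 3 for erythroid, 0 and 1 for interferon response, 2 and 2 for AP-1 and immediate early, and 1 and 3 for stromal and endothelial genes. The larger count changed sides with equal numbers of peaks for HSC aging genes (5 and 1, and 4 and 1 after thinning) and granulocyte and monocyte genes (1 and 0). Regions within 1 kb of a gene end made up 5.61% of gained and 5.02% of lost regions (odds ratio 1.13, Fisher's exact test, Benjamini-Hochberg adjusted p = 0.670). The total of 3074 lay above the 2443 and 2524 of the other splits of these libraries. With only 3 splits the share cannot fall below 0.333. Gains made up 37.1% of the total as deposited, 43.9% after thinning to equal depth (1395 against 1786) and 50.9% with equal numbers of peaks (1443 against 1394). With MUT T1 replicate 1, MUT T1 replicate 2, WT T1 replicate 1 or WT T1 replicate 2 left out in turn, gained regions numbered 2698, 5310, 2191 and 2793. Lost regions numbered 8396, 2882, 4964 and 4967 in the same order, and counts grow because fewer calls were then required.

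MUT T2 against WT T2 asks the same of the T2 population. The region inside Itga6 was again called in both MUT and neither WT libraries, with the highest smaller fold enrichment of all gains (11.9). Next came regions near Rnase2b, a gene of the eosinophil-associated ribonuclease family (11.8), near Prdm8 (11.4) and inside Uqcc1, an assembly factor gene of respiratory complex III (11.1), then Ints10, Odf3l2, Fmn1 and Prpf6 at 10.2 to 10.5. The Mid1 region was again called in both WT and neither MUT libraries (12.5), as was a region inside Pex14, which encodes a peroxisomal import protein (9.83). Zfp385b, Nudt11, Atp10a, Ptprn2, Chst1 and 2210010C04Rik followed among the losses at 8.29 to 9.28. In total 3585 regions were gained and 415 lost, and the WT T2 libraries had a lower background (2.45 and 1.89) than the MUT T2 libraries (3.21 and 3.10).

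In MUT T2 against WT T2, HSC identity genes had 7 gained regions, among them 2 at Mecom and 1 each at Mllt3, Hlf, Hoxa10 and Slamf1. HSC identity genes had 4 lost regions, at Erg (3.84), Mllt3 (3.77), Runx1 (3.60) and Mecom (2.00). Their gained share of 63.6%, against 90.0% at other genes, did not pass after adjustment (odds ratio 0.195, Fisher's exact test p = 0.0189, Benjamini-Hochberg adjusted p = 0.493). With equal numbers of peaks the list passed, with 2 gained regions and 16 lost, among them 3 each at Erg, Mecom and Prdm16 (gained share 11.1% against 53.8%, odds ratio 0.107, Fisher's exact test, Benjamini-Hochberg adjusted p = 0.0222). Set against random gene lists matched on their regions, the list as deposited had an adjusted p of 0.0208 (Benjamini-Hochberg). After thinning to equal depth it had 5 gained and 5 lost regions and an adjusted p of 1.00 by Fisher's exact test with Benjamini-Hochberg. HSC aging genes had 12 gained and 0 lost regions, including Cd38, an NAD-degrading ectoenzyme gene (7.80), Plscr2 (5.85), Vwf and Itga6. TGF-beta and niche signalling genes had 14 gained, such as Acvr1 (6.21), and 0 lost. Granulocyte and monocyte genes had 8 and 0 (Fcgr3, 5.88), stromal and endothelial genes 8 and 0 (Fbln1, 7.16), and cell cycle and survival genes 8 and 1, with a gain at Rb1 (6.17) and a gain and a loss at Bcl2 (loss 4.57). B lymphoid genes had 5 and 1 (3 gains and a loss at Bach2, loss 3.48), T and NK lymphoid genes 3 and 0, erythroid genes 4 and 0 (Sptb, 5.70), and megakaryocyte and platelet genes 4 and 0. Inflammation and NF-kB genes had 4 and 0, interferon response genes 3 and 0, and AP-1 and immediate early genes 3 and 0 (Atf3, 6.04). With equal numbers of peaks the larger count changed sides for TGF-beta and niche signalling genes (5 gained and 6 lost), B lymphoid genes (2 and 3), T and NK lymphoid genes (0 and 4), megakaryocyte and platelet genes (3 and 4) and cell cycle and survival genes (4 and 5), as for HSC identity genes. Gained regions lay within 1 kb of a gene end less often than lost ones (4.30% against 7.71%, odds ratio 0.537, Fisher's exact test, Benjamini-Hochberg adjusted p = 0.00843). Within 2 kb the odds ratio was 0.743 (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.132). The total of 4000 lay above the 2518 and 1928 of the other splits. Gains made up 89.6% of it as deposited, 79.7% after thinning (2648 against 674) and 54.2% with equal numbers of peaks (1551 against 1313). With MUT T2 replicate 1, MUT T2 replicate 2, WT T2 replicate 1 or WT T2 replicate 2 left out in turn, gained regions numbered 6890, 8771, 8526 and 5967. Lost regions numbered 1645, 1052, 1535 and 2556 in the same order.

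**Figure D3:**
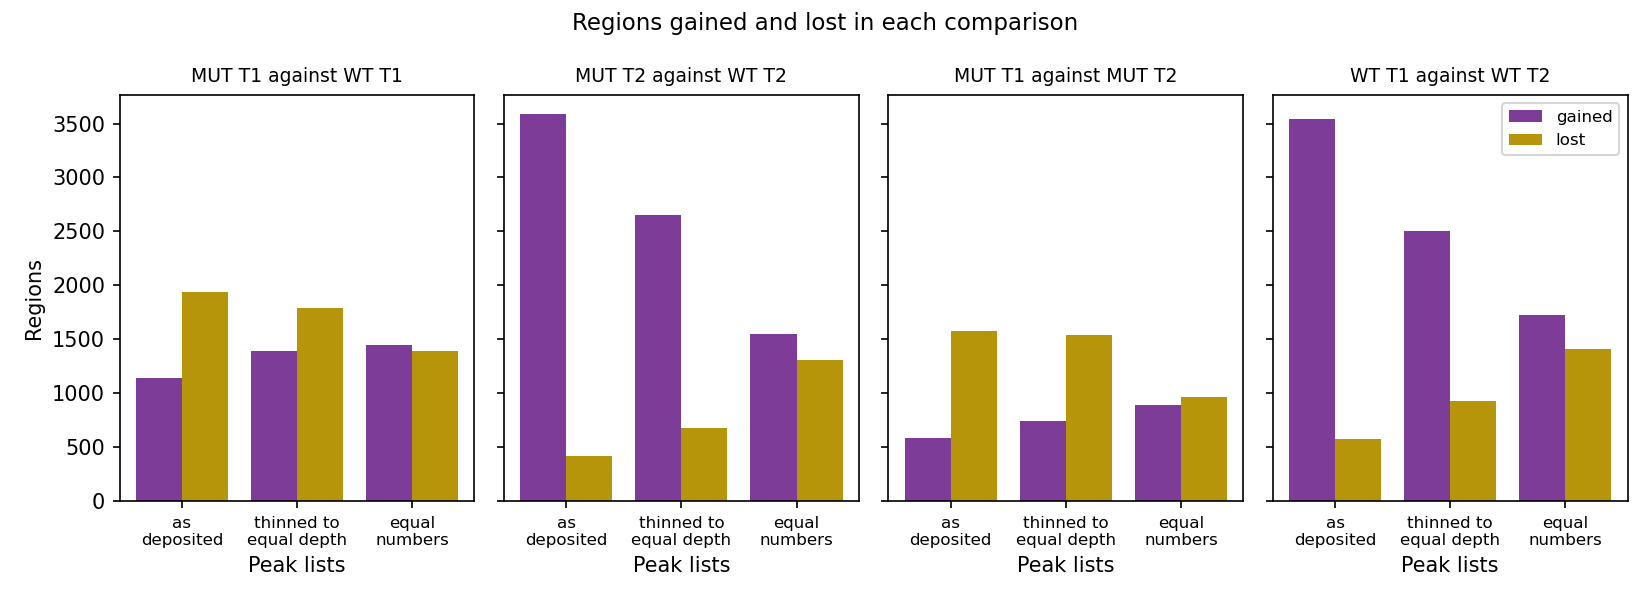
Number of regions gained and lost (vertical axis, bars from 0) in each of the 4 comparisons of 2 groups, for the lists as deposited, thinned to equal depth and with equal numbers of peaks. In MUT T2 against WT T2 the bars go from 3585 gained and 415 lost as deposited to 1551 and 1313 with equal numbers of peaks.

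Some regions differed between MUT and WT in both populations. Of 426 such regions, 201 were gained in both, including Itga6 and Ptprt, and 55 were lost in both, including Mid1 and Rims2. A further 160 were lost in T1 and gained in T2, and 10 the reverse (56 and 54 with equal numbers of peaks, 117 and 27 after thinning). MUT T1 replicate 2 and both WT T2 libraries, the shallowest, stand on the same side of this division. In the lists as deposited 60.1% shared a direction (odds ratio 6.91, Fisher's exact test p = 8.31e-10). Independent lists of these sizes, drawn from all 90736 regions, would share 45 regions gained in both, 8.85 lost in both, 76.4 lost in T1 and gained in T2, and 5.21 the reverse. The 49577 regions called in all 8 libraries cannot differ, so these expected counts are too low. An excess over them, in the same or in opposite directions, cannot be read as a result. Regions are also not replicates. Of the 9 ways to pair a split of the T1 libraries with a split of the T2 libraries 2 gave a log2 odds ratio as far from 0: 2.73 for MUT against WT and 3.28 for replicate 1 against replicate 2. The odds ratio was 3.60 with equal numbers of peaks, 3.92 after thinning and 2.82 with summit windows. Without MUT T1 replicate 1, MUT T2 replicate 1, MUT T2 replicate 2, WT T1 replicate 1, WT T2 replicate 1 and WT T2 replicate 2 it was 2.16, 2.90, 2.03, 4.17, 4.37 and 4.16.

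All MUT against all WT asks what separates the genotypes in both populations. The 10 strongest of the 201 regions called in all 4 MUT and no WT libraries were assigned to Itga6 (lowest fold enrichment 10.9), Ptprt (10.1), the cytochrome P450 gene Cyp4a12a (7.57), Scimp (7.30), Plekha5 (7.26), Ect2l (6.68), the LIM-domain gene Lmo3 (6.58), the ribonuclease gene Ear6 (6.26), the homeobox gene Gsc (6.17) and the mannosidase gene Man2a1 (6.09). Of the fixed lists, further gained regions were near Nr4a3, an orphan nuclear receptor gene (3.65), and inside Tbx21, which encodes the T-bet factor of T and NK cells (3.29). The 10 strongest of the 55 regions called in all 4 WT and no MUT libraries were assigned to Mid1 (11.3), the synaptic gene Rims2 (7.60), Pex14 (7.32), Oxr1 (7.25), Samd4 (7.15), Kcnip4 (6.76), the RNA exosome gene Exosc10 (5.90), Trim9 (5.89), Vmn2r87 (5.83) and the nucleoside transporter gene Slc28a2 (5.42). Mid1 spans the pseudoautosomal boundary. A region of chromosome Y, outside these counts, was called in all 4 MUT and no WT libraries, the reverse of Mid1. Chromosome 14 held 33 of the 256 regions (12.9%), 27 gained and 6 lost, against 3.70% of the other regions called in exactly 4 libraries (odds ratio 3.85, Fisher's exact test p = 4.24e-09, Benjamini-Hochberg adjusted p = 8.48e-08 over chromosomes). Of these 33, 30 lay before 70 Mb, as did 89 of the 147 other regions of chromosome 14 called in exactly 4 libraries. Of the 35 splits of the libraries into 4 and 4, 3 had as many regions. Within replicate 1 libraries, 2754 regions were called in both MUT and neither WT libraries and 760 the reverse (highest total of the other splits 2290), and within replicate 2 libraries 1315 and 1271 (highest other 3855). Gained regions numbered 539, 313, 334, 384 and 326 without MUT T1 replicate 2, MUT T2 replicate 2, WT T1 replicate 1, WT T1 replicate 2 and WT T2 replicate 1. Lost regions numbered 122, 119, 83, 93, 119 and 164 without MUT T1 replicate 1, MUT T2 replicate 1, MUT T2 replicate 2, WT T1 replicate 1, WT T2 replicate 1 and WT T2 replicate 2.

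**Figure D4:**
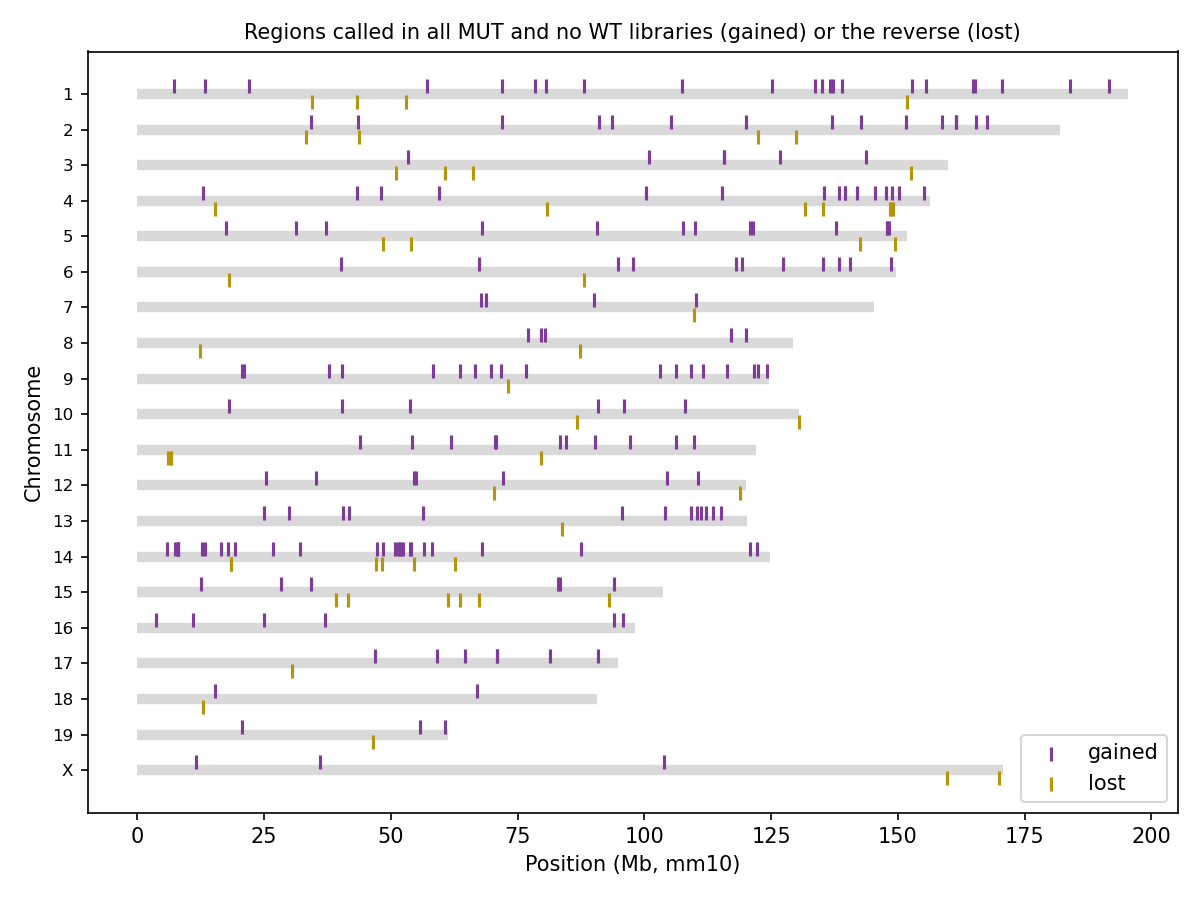
Position in Mb of mm10 (horizontal axis) of the regions called in all MUT and no WT libraries (gained, 201) or the reverse (lost, 55), by chromosome (vertical axis). Chromosome 14 carries 33 of the 256 regions, 30 of them before 70 Mb.

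MUT T1 against MUT T2 compares the populations within MUT mice. Regions called in both MUT T1 and neither MUT T2 libraries lay inside Rhag, an erythrocyte membrane gene (9.56), inside Klhl32 (8.57), near Rbpj, the DNA-binding factor of Notch signalling (8.21), and near the T-cell costimulator gene Icos (7.25). Zc3hav1, Pir, Usp34 and Oprl1 had 6.59 to 7.30. Lost regions were led by those inside the ubiquitin ligase gene Rnf130 (12.8), inside Mettl7a3 (10.97), near Amtn (9.97) and inside Nebl (9.75), with Krt28, Fcho2, Slc16a12 and Upp2 at 9.02 to 9.26. In total 582 regions were gained and 1581 lost, a total of 2163 beside the 3775 and 2213 of the other splits. The order changed after thinning (2281 beside 3260 and 2190) and with equal numbers of peaks (1856 beside 2725 and 1818), where the total lay above 1 of the other splits.

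HSC aging genes had 1 gained region, at Runx1t1 (3.65), and 7 lost regions in MUT T1 against MUT T2, at Gda (4.75), Fhl1 (4.34), Alcam, Jam2, Nupr1, Stat3 and Vwf. HSC identity genes had 4 and 8, with a gain at Mllt3 (5.68) and a gain and a loss at Gfi1b (loss 5.49). Cell cycle and survival genes had 1 and 8, with a gain at the cell cycle inhibitor gene Cdkn1c (2.81) and a loss at Mki67 (4.39). TGF-beta and niche signalling genes had 3 and 8, with gains at Tgfbr1 (5.62) and Tgfbr2 (3.62), losses at Cxcr4 (5.12) and Tgfbr3 (4.75), and 2 losses at Tgfbr2 as well. The others had 0 and 1 (B lymphoid), 2 and 3 (T and NK lymphoid, with a gain at Themis, 5.02, and a loss at Il2rb, 4.02), 0 and 1 (granulocyte and monocyte), 2 and 2 (erythroid, gain at Sox6, 3.88), 1 and 3 (megakaryocyte and platelet, loss at Cd9, 4.21), 1 and 4 (inflammation and NF-kB), 0 and 1 (interferon response), 0 and 0 (AP-1 and immediate early) and 0 and 2 (stromal and endothelial). With equal numbers of peaks the larger count changed sides for HSC identity genes (8 gained and 3 lost), T and NK lymphoid genes (5 and 0, and 3 and 2 after thinning), megakaryocyte and platelet genes (3 and 1), cell cycle and survival genes (3 and 2), inflammation and NF-kB genes (3 and 2) and TGF-beta and niche signalling genes (8 and 4). Gained and lost regions lay within 1 kb of a gene end equally often (6.01% each, Fisher's exact test, Benjamini-Hochberg adjusted p = 1.00). Gains made up 26.9% of the total as deposited, 32.4% after thinning (739 against 1542) and 48.2% with equal numbers of peaks (894 against 962). With MUT T1 replicate 1, MUT T1 replicate 2, MUT T2 replicate 1 or MUT T2 replicate 2 left out in turn, gained regions numbered 1875, 4218, 2202 and 1474. Lost regions numbered 7755, 2595, 4088 and 5378 in the same order.

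WT T1 against WT T2 compares the populations within WT mice. Regions called in both WT T1 and neither WT T2 libraries lay inside the cell division gene Cdca2 (13.4), inside Smc1b, a meiotic cohesin gene (12.4), inside Fmn1 (11.7) and near Tnfsf10, which encodes the death ligand TRAIL (10.8). Prune2, Kcnip4, Uqcc1 and Olfr701 had 10.9 to 11.2. Lost regions lay inside Filip1l, where the smaller fold enrichment of 29.3 exceeded that of every other named region, near Slc25a54 (12.4), inside Akap14 (11.02), near Zbed4 (10.4) and near the chemokine gene Cxcl5 (8.98), with Hmcn1, Dennd1a and Nudt11 at 8.99 to 10.2. In total 3543 regions were gained and 573 lost, and the WT T2 libraries had the lower background (2.45 and 1.89, against 3.24 and 3.29).

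HSC identity genes had 18 gained and 9 lost regions in WT T1 against WT T2, with 5 gains and 2 losses at Mecom (strongest loss 4.25), 3 gains at Hlf, losses at Kit (4.63), Mllt3 (3.77) and Prdm16 (3.03), and 1 gain each at Mllt3 and Prdm16. Their gained share of 66.7%, against 86.5% at other genes, did not pass after adjustment (odds ratio 0.313, Fisher's exact test p = 0.00740, Benjamini-Hochberg adjusted p = 0.385). HSC aging genes had 5 and 0, with gains at Cd38 (9.32) and Ptprk (6.76). TGF-beta and niche signalling genes had 10 and 0, with the region inside Acvr1 that was called in both WT T1 libraries and no other (9.25). T and NK lymphoid genes had 7 and 0, with gains at Themis (7.46) and Bcl11b, a paralogue of Bcl11a needed in T cells (7.40). Cell cycle and survival genes had 9 and 1, with a gain at Bcl2l1 (6.39) and a gain and a loss at Rb1 (loss 4.93). B lymphoid genes had 6 and 1 (2 gains and a loss at Bach2, loss 3.48), granulocyte and monocyte genes 4 and 0, erythroid genes 4 and 0 (Sox6, 6.13), and megakaryocyte and platelet genes 6 and 2. Inflammation and NF-kB genes had 5 and 0, interferon response genes 2 and 0, AP-1 and immediate early genes 4 and 0, and stromal and endothelial genes 5 and 0 (Fbln1, 6.37). In lists of equal numbers the larger count changed sides for HSC identity genes (4 gained and 11 lost, and 9 and 8 after thinning), B lymphoid genes (2 and 3) and granulocyte and monocyte genes (0 and 3, and 2 and 3 after thinning). Over the 52 tests of 13 lists in 4 comparisons, 0 passed Fisher's exact test with Benjamini-Hochberg adjustment. Of them, 2 had an unadjusted p under 0.05 (HSC identity in MUT T2 against WT T2 and in WT T1 against WT T2), and 1 passed against matched random lists. Both of these comparisons hold the same 2 WT T2 libraries, which were among the shallowest, so they are not independent. Gained regions lay within 1 kb of a gene end less often than lost ones (4.40% against 8.03%, odds ratio 0.528, Fisher's exact test, Benjamini-Hochberg adjusted p = 0.00206). MUT T2 against WT T2, which shares the WT T2 libraries, had a like odds ratio (0.537). The comparisons without these libraries had odds ratios of 1.13 (MUT T1 against WT T1) and 1.00 (MUT T1 against MUT T2). Within 2 kb the odds ratio was 0.738 (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.132). The total of 4116 lay above the 2289 and 1793 of the other splits. Gains made up 86.1% of it as deposited, 73.0% after thinning (2508 against 927) and 55.0% with equal numbers of peaks (1724 against 1411). With WT T1 replicate 1, WT T1 replicate 2, WT T2 replicate 1 or WT T2 replicate 2 left out in turn, gained regions numbered 7556, 7375, 8553 and 5821. Lost regions numbered 1283, 1670, 1836 and 2970 in the same order.

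The libraries also divided by replicate number at loci of the sex chromosomes, which were examined after the lists had been seen. A region of the Xist locus, the non-coding RNA gene that silences an X chromosome in female cells, was called in all 4 replicate 2 libraries and no replicate 1 library (X, 103481345 to 103482331, fold enrichment 3.72 to 4.705). As merged regions, those starting at 103477436 and 103483184 did not divide this way: each was called in all 4 replicate 2 and in 3 replicate 1 libraries. Their fold enrichment in replicate 1 reached 9.67 and 6.84. The region starting at 103483184 joins unlike peaks, however. Its replicate 2 peaks start at 103483184 to 103483199 and lie over the gene end at 103483233. Its replicate 1 peaks start at 103484202 to 103484211, outside the gene, so peaks over this end did divide by replicate number. A further one, starting at 103459873, was called in MUT T2 replicate 2 alone. Of 36 regions called in all replicate 2 and no replicate 1 libraries, 24 (66.7%) lay on X, against 3.29% of other regions called in exactly 4 libraries (odds ratio 58.8, Fisher's exact test p = 1.52e-26). These were 14 regions inside the non-coding RNA gene Firre and 2 inside the adjacent gene Gm35612, 7 inside 4933407K13Rik, the Dxz4 locus, and the 1 at Xist that divided the libraries. At Firre with 15 kb on each side, replicate 1 libraries had 1 of 19 regions each and replicate 2 libraries 18 or 19. Each of the 4 groups holds 1 library of each replicate number.

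**Figure D5:**
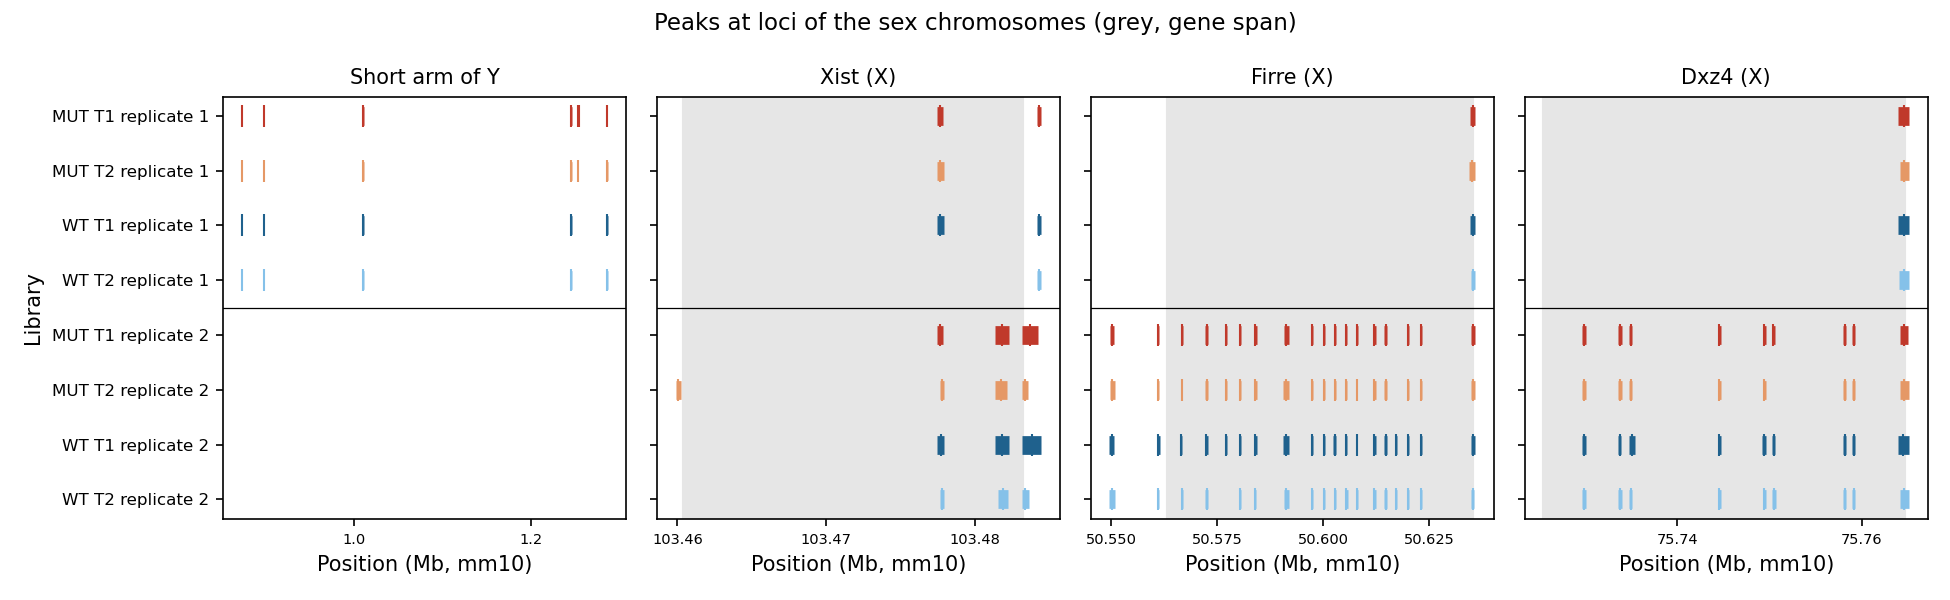
Peaks (bars) of the 8 libraries (vertical axis, ordered by replicate number) at loci of the sex chromosomes, by position in Mb of mm10, with gene spans in grey. At Firre the replicate 1 libraries have 1 of 19 regions each and the replicate 2 libraries 18 or 19.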

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

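The tests of the sex chromosomes and the choice of the genes named here were made after the values had been seen.

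Chromosome Y is outside the regions compared between groups. There 5 regions were called in all 4 replicate 1 libraries and in no replicate 2 library. They lie at or near single-copy genes of the short arm, which are broadly transcribed in males. The nearest gene was Kdm5d, a histone demethylase gene, for the regions starting at 872808 (24504 bp away) and 897477, the translation factor gene Eif2s3y for that at 1009906, Uty for that at 1244627 and the helicase gene Ddx3y for that at 1285638. The region at Eif2s3y had a fold enrichment of 11.4 to 14.1 in the 4 libraries. Another Y region did not divide by replicate number (90761351 to 90761817, 16501 bp from the nearest gene, Gm52481). It was called in all 4 MUT libraries (fold enrichment 6.41 to 10.3) and in no WT library. This is the reverse of the Mid1 region on X, in a gene that spans the pseudoautosomal boundary. Whether these 2 calls are related was not tested.

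A difference in depth as the whole cause is argued against, because in 4 pairs a library without the short-arm Y peaks had a higher background than one with them. WT T1 replicate 2 had 0 such regions at a background of 3.29, and WT T2 replicate 1 had 5 at 2.45. Replicate 1 libraries were deeper on average, however (mean background 3.07 against 2.58), so depth runs partly with the Y peaks. A difference in the sex of the donor mice is a candidate explanation, with male donors for replicate 1 and female donors for replicate 2. In line with it, 65.7% of the 35 regions outside Xist called in every library without short-arm Y peaks and in none with them lay on X, against 3.29% of other regions called in exactly 4 libraries (Fisher's exact test p = 2.64e-25), although the 23 on X lie at or beside Firre and Dxz4 alone and are not independent. The sex of the mice is not given in the sources used here, and a mixture of donors in any library was not tested. Since each group holds 1 library of each replicate number, sex would add to the spread within every group and would not favour MUT or WT.

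A total of 170 regions differed between MUT and WT in opposite directions in T1 and T2. For a single region the difference between the populations was not tested, and as a division of the 8 libraries into 4 and 4 this count was reached by 7 of the 35 splits (highest other 398). The 10 that were gained in MUT T1 and lost in MUT T2 had as nearest genes Unc93a2, Ripk2, Sema5a, Vsir, Hs3st3a1, Tbk1, Fgf14, Golga5, Lpp and Mecom. There were 54 of this kind and 56 of the reverse with equal numbers of peaks, and 27 and 117 after thinning. The 160 that were lost in MUT T1 and gained in MUT T2 in the lists as deposited include regions at Nebl (smallest fold enrichment 8.62) and Ablim3 (6.55).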

How the results depend on the processing

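Thinning to equal depth and leaving out chromosome 14 were chosen after the results were seen, and the other alternatives were part of the design. Under the stricter peaks 23 of 23 results kept their direction, their side of the threshold or a count within 1.5 times, as did 12 of 12 on autosomes only, 3 of 3 without chromosome 14 and the gene lists within 10 kb. The same held for 21 results after thinning, 14 with equal numbers of peaks, 10 with 50% overlap and 10 with summit windows. The exceptions follow, and where no reason is given the cause was not tested.

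With equal numbers of peaks, which shortens the lists of the deeper libraries by construction, gained and lost regions were 1551 and 1313 in MUT T2 against WT T2, 894 and 962 in MUT T1 against MUT T2, and 1724 and 1411 in WT T1 against WT T2. Gained and lost counts were scored apart, so MUT T1 against WT T1 is not among these exceptions. Its larger count nevertheless changed sides, from 1140 gained and 1934 lost to 1443 and 1394. With 50% overlap the gained regions were 5763 in MUT T2 against WT T2 and 6032 in WT T1 against WT T2. With summit windows the lost regions were 805 and 1073 in these comparisons, and after thinning 674 and 927. The number of gene lists passing was 1 with equal numbers and 1 against matched random lists, in place of 0. Within 2 kb of gene ends the odds ratios of 0.743 (MUT T2 against WT T2) and 0.738 (WT T1 against WT T2) no longer passed (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.132 for each).

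Leaving out 1 library relaxes what a gained region requires, so counts grow by construction. Gained and lost regions then ranged from 2191 to 5310 and 2882 to 8396 in MUT T1 against WT T1, 5967 to 8771 and 1052 to 2556 in MUT T2 against WT T2, 1474 to 4218 and 2595 to 7755 in MUT T1 against MUT T2, 5821 to 8553 and 1283 to 2970 in WT T1 against WT T2, and 280 to 539 and 73 to 164 in all MUT against all WT. The difference in Jaccard index between same-group and other pairs ranged from −0.00244 to 0.0367 and passed without MUT T1 replicate 1 (0.0367) or MUT T1 replicate 2 (0.0225). Both of these omissions remove the MUT T1 pair, which had the lowest index of all.

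Deviations from the group mean of the libraries with the same number correlated at −0.00407 to 0.0565 between groups, all below 0.1, so the numbers were not taken as pairs. This correlation, over 30646 regions, cannot exclude a trait shared by number at few loci, and loci of the sex chromosomes did divide by number. Replicate 1 against replicate 2 also gave the log2 odds ratio farthest from 0 (3.28) among the 9 pairings of T1 and T2 splits. With the number as a block, the difference in peaks between MUT and WT was 2572 (exact permutation p = 0.5), and 2 of 8 splits had as many regions as MUT against WT. Low depth limits MUT T1 replicate 2 and both WT T2 libraries, where a region that is not called may be open. The motif tests and their alternatives were not run for lack of a genome sequence, nor was assignment by transcript start, and equal numbers of peaks give no test of peaks per library.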

Other observations

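The tests of splits, of crowding and of chromosome 14, and thinning to equal depth, were chosen after the results had been seen.

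Regions called in all T1 and no T2 libraries, or the reverse, were few: 46 and 24, a total of 70, and 29 of the 35 splits had as many (highest other 398). Chance is not excluded for them, and no excess of regions that separate T1 from T2 in both genotypes was detectable with these lists.

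The regions that separate all MUT from all WT libraries, such as those at Itga6, Ptprt and Mid1, totalled 256, and 3 of 35 splits had as many, so chance is not excluded (the highest other, with 398, put the 4 libraries MUT T1 replicate 1, MUT T2 replicate 1 and both WT T1 together, which are the deepest). A difference in depth as the whole cause is argued against: the 9 other splits that also put MUT T1 replicate 2 opposite both WT T2 libraries exchange only libraries of like depth (background 3.10 to 3.38), and the 256 regions were 2.44 times the highest of these (2.06 with equal numbers of peaks), although 6 of the 9 had as large a difference in background. An inherited segment of chromosome 14 that differs between the MUT and WT mice is a candidate explanation for part of it: regions that differ in only 1 population also lay on chromosome 14 more often than regions of the mixed splits, with odds ratios of 1.42 in T1 (4.54% against 3.24%, Fisher's exact test p = 0.00407) and 1.35 in T2 (5.13% against 3.85%, Fisher's exact test p = 0.00592), each with a Benjamini-Hochberg adjusted p of 0.0118. Between T1 and T2 the odds ratios were 0.961 within MUT and 1.06 within WT. The shares on chromosome 14 there were 4.07% and 4.47%. The T1 share of 4.54% was close to these, and its mixed splits had a low share, so this support is weak. For segments over the whole genome the test leaves it open, with 29.3% of the regions within 1 Mb of another against 24.4% in random draws (permutation p = 0.0915), and 23.8% against 22.5% without chromosome 14 (permutation p = 0.382). Without chromosome 14 there were still 174 gained and 49 lost regions, for which an effect of the Bcl11a genotype itself stays open and untested.

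Gained and lost regions were unequal in number in every comparison of 2 groups, and the deeper group always had more. A difference in depth could account for this in whole or in part: drawing the peaks down to the same background lowered the median absolute log2 ratio of gained to lost regions from 2.04 to 1.25 (1.24 to 1.37 over 20 random draws). A bound of 1.02, at or above which depth was to be excluded, had been set beforehand, but it assumed that the draw removes depth. It did not do so, since the 3 shallowest libraries still had the shortest lists (62231 to 65925 peaks, against 67298 to 70609) and the sign still followed depth in all 4 comparisons, so depth and other traits of these libraries cannot be told apart. With equal numbers of peaks the median was 0.17, which equal list lengths nearly force.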
